A study of Prunus sibirica with 6 samples.

How the data were processed

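Gene expression was measured by RNA sequencing in frosted flowers of Prunus sibirica, with 3 libraries of a clone with strong frost resistance (clone 338) and 3 of a clone with weak frost resistance (clone 28). Libraries were assigned to clones from the group label of each sample and numbered as in the labels, and each column of the table was matched to its sample by name. No unfrosted sample was analysed here, so the comparison is between frosted clones.

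The authors deposited a table of FPKM values, read fragments per kilobase of gene scaled to library size, for 31889 genes, with gene position, length and description. Per the submitters' processing notes, the tools were CASAVA, RSEM and Bowtie2, and their versions and the genome build are not given in the sources used here. The genes carry positions on 8 linkage groups and on further contigs, and coordinates are given as in the deposited table. Of the genes, 1453 carry identifiers outside the PARG series. Names of genes are those of the protein descriptions in the table, which are similarities to proteins of other species. Reads shared between members of a gene family could have been assigned to a member or left out in ways that the table does not show.

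The deposited FPKM values were checked for the reads behind them. In each library, 100% of the positive values multiplied by gene length were whole multiples of a single step, within 0.01 read, so that whole reads per gene could be computed. Their sums were 16865237, 16517153 and 18866306 reads in strong libraries 1, 2 and 3, and 16775697, 16367632 and 17220413 reads in weak libraries 1, 2 and 3. The effective library size behind each column was not its sum of reads but its median-of-ratios factor times the geometric mean of the sums. It stood at 1.35, 1.18 and 1.42 times the reads in the strong libraries and at 0.618, 0.663 and 1.21 times the reads in weak libraries 1, 2 and 3. The deposited values are therefore scaled between libraries by the typical gene. Abundant transcripts in weak libraries 1 and 2 raise their summed FPKM to 1217398 and 1106483, against 464129 to 591204 in the strong libraries and 580337 in weak library 3. For a gene of 1 kilobase, 1 read was worth 0.0372 to 0.0965 FPKM. Fold bounds for genes with 0 reads in a clone were computed against 3 reads over its 3 libraries and cover counting error only.

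Before averaging, the libraries were compared in pairs, and all pairs differed by more than sampling noise, so none was a copy of another. Each was counted as a replicate, as numbered in the labels, which leaves open whether they are separate trees or separate preparations. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (16462 genes) with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), by lmFit and eBayes with trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are strong minus weak on that scale, which understates the change of low genes, with the standard error of the fit, while FPKM values are means with SD over 3 libraries. A further count asked for a difference of at least 1 on the log2 scale. Genes listed in one clone only had at least 1 FPKM in all 3 libraries of the clone and under 0.1 in all 3 of the other, with no test. Single values per library were compared by exact permutation tests.

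Gene lists (33) were formed by word patterns in the descriptions, and each had at least 5 tested genes. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation no list passed (smallest adjusted p = 0.697), and fry called 1 list, the antioxidant enzymes. Patterns can match genes outside the intended group, and 115 genes stood in more than 1 list. The named genes were those with an adjusted p under 0.05, a difference of at least 1, a mean of at least 5 FPKM in the higher clone and no overlap between the clones' libraries. Of these, the rule took the 10 largest differences in each direction and up to 4 per list with the smallest adjusted p. It added up to 4 S-RNase, CBF or DREB, ICE1 and dehydrin genes of any result. This gave 136 genes, and the others named are said to have been chosen after their values were seen or are the most abundant genes of the table.

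The test was run on simulated data before it was used. Among 15963 simulated genes with 200 changed, it called 1.32% of those changed 2-fold, 55.6% of those changed 4-fold and 75.4% of those changed 8-fold, and 3.49% of its 86 calls were unchanged genes. Simulated errors were drawn separately for each gene and library, without the shared structure of the real libraries. The share of unchanged genes in the simulation is therefore not the error rate of the real calls. With 86 calls against 2520 in the real data, its adjusted threshold was also stricter. The shares of changed genes that it called are therefore not the power of the real test. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, library weights, the replicate number as a block and leaving out each library. A limma-voom fit on the whole reads, fits with the pollen list mean or the LAT52 gene as a covariate, a comparison with weak library 3 alone and a test of protein families were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.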

Results

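RNA was sequenced from flowers of Prunus sibirica, the Siberian apricot, a tree that blooms early in spring when frost is common. The flowers were taken at bloom while they were under natural frost at -4 °C. Clone 338, which has strong frost resistance, and clone 28, which has weak frost resistance, gave 3 libraries each. Resistance was thus compared in a single clone of each kind, and cannot be told apart from other differences between these clones. Every flower had been exposed to frost. The libraries held 16367632 to 18866306 reads assigned to genes, and 31889 genes were listed, of which 22755 (71.4%) carried a protein description. Nothing in the labels states that the 3 libraries of a clone came from separate trees, so p-values measure only the spread between these samples, which may be technical.

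The 10 most abundant genes, of which 3 had no description, had their highest FPKM in libraries 1 and 2 of the weak clone. A putative pectinesterase/pectinesterase inhibitor 28 (PARG29387) was listed at 14770, 13365 and 4409 FPKM (read fragments per kilobase of gene, scaled to library size, as deposited) in weak libraries 1, 2 and 3, and at 2667, 4463 and 1721 FPKM in strong libraries 1, 2 and 3. The homolog of the tomato anther-specific gene LAT52 (PARG10934) averaged 6341 ± 3473 FPKM in the weak clone and 1705 ± 813 FPKM in the strong clone (SD, n = 3). A defensin-like gene (PARG06946), fasciclin-like arabinogalactan protein 14 (PARG08021) and the signalling peptide gene RALF-like 22 (PARG12203) were also most abundant in weak libraries 1 and 2. Their log2 differences, strong minus weak, were -1.48 ± 0.99, -1.61 ± 0.97 and -1.53 ± 0.90 (SE). None of these 5 genes passed the test, with limma adjusted p values of 0.197, 0.148, 0.260, 0.218 and 0.210 in the order named. The 10 top genes of each library, which were ranked within that library and are not the same in all, took 9.79%, 9.52% and 6.70% of the summed FPKM in the weak libraries and 5.19%, 6.73% and 4.40% in the strong libraries (exact permutation p = 0.2, two-sided, where 3 against 3 cannot go below 0.1).

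Over the 72 tested genes of the pollen list, the mean log2(FPKM + 1) was 5.79, 5.67 and 5.41 in the weak libraries and 5.11, 5.41 and 4.83 in the strong libraries (exact permutation p = 0.1), with weak library 3 just above strong library 2 before rounding. The photosynthesis list, a marker of green parts of the flower, ran the other way, at 4.20, 4.75 and 5.26 in the weak libraries and 5.57, 5.56 and 5.67 in the strong libraries (exact permutation p = 0.1). Weak library 3 stood apart from its group. Across genes, which are not independent replicates, its log2 values had Pearson correlations of 0.918, 0.925 and 0.895 with strong libraries 1, 2 and 3. Its correlations with weak libraries 1 and 2 were 0.849 and 0.861, while the latter pair had 0.986. The first principal component held 86.4% of the variance and placed weak library 3 at -15.9, between the strong libraries, at -77.4, -46.7 and -93.5, and weak libraries 1 and 2, at 124.0 and 109.5. Between 15059 and 16066 genes reached 1 FPKM per library, with a mean difference of 455 genes between the clones (exact permutation p = 0.3).

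**Figure D1:**
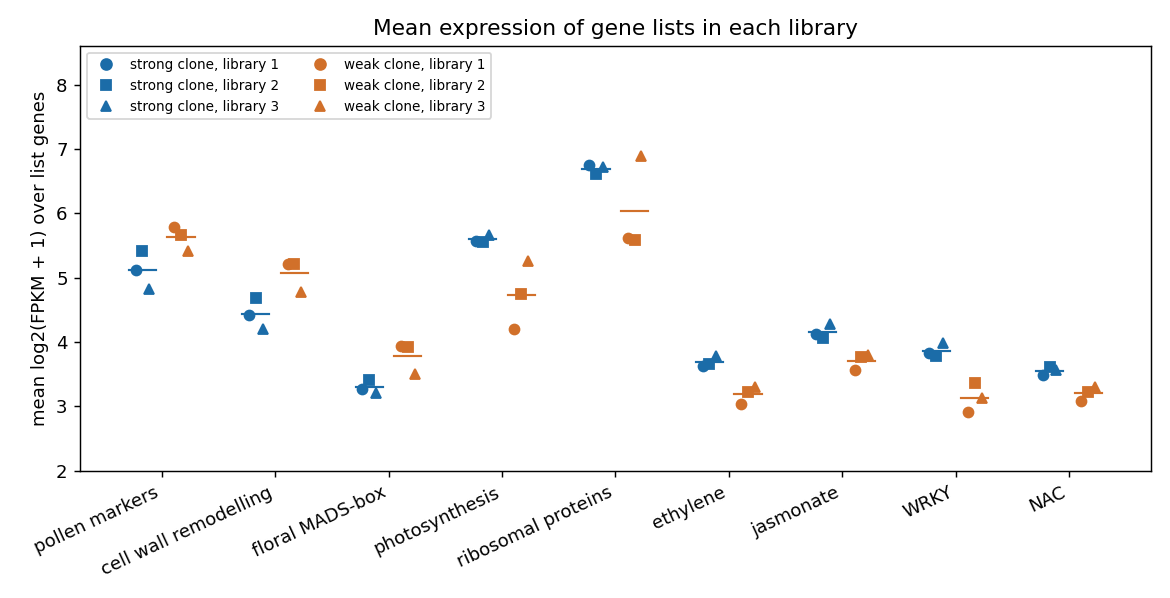
Mean log2(FPKM + 1) over the tested genes of 9 gene lists, with 1 point per library (3 per clone) and a short line at each clone's mean. The pollen, cell wall and MADS-box lists lie higher in the weak clone, the photosynthesis list lies higher in the strong clone, and weak library 3 has a pollen mean of 5.41, just above that of strong library 2.

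The comparison that the design sets up asks which genes were expressed differently in frosted flowers of the resistant and the sensitive clone. Flowers of the strong clone had higher levels of single genes for immune receptors and for WRKY, NAC and ethylene response factors, and lower levels of single genes for pectin breakdown and surface lipids. RRS1 (PARG20786, linkage group 6, 5742611 to 5745429) is named for its similarity to an immune receptor with a WRKY domain, a domain that was not checked in this gene. It was at 43.2 ± 7.07 FPKM in the strong clone (SD, n = 3) and had 1 read in all 3 weak libraries together. The log2 difference was 5.45 ± 0.20 (SE, limma adjusted p = 0.000598). RRS1 is among the genes listed in the strong clone only, where a difference in sequence or gene copies cannot be told apart from expression. A TMV resistance protein N gene (PARG22399, linkage group 6), of the same receptor class, was at 44.8 ± 7.86 FPKM against 0.67 ± 0.828. In the opposite direction, dnaJ chaperone 10 (PARG21558, linkage group 6) was at 0.625 ± 0.222 FPKM in the strong clone and 190.0 ± 101 in the weak clone (log2 difference -6.69 ± 0.48, adjusted p = 0.00226). A GDSL lipase gene (PARG12119, linkage group 3) was at 2.25 ± 1.202 and 346 ± 233 FPKM (-6.58 ± 0.54, adjusted p = 0.00299).

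Among 16462 genes tested, 2520 differed between the clones by limma at an adjusted p below 0.05, of which 1239 were higher and 1281 lower in the strong clone. With a difference of at least 2-fold on the log2(FPKM + 1) scale in addition, 2205 genes remained, 1049 higher and 1156 lower. In 7481 genes (45.4%), 3838 higher and 3643 lower, the libraries of the clones did not overlap, where chance gives 10% for a single gene. All genes share the same libraries and can separate together, so these are not independent events. These counts rest on single libraries. Leaving out strong library 1, 2 or 3 gave 166, 353 and 230 genes, and leaving out weak library 1, 2 or 3 gave 610, 395 and 12075. Adding the pollen list mean as a covariate gave 59 genes, of which 57 were among the 2520. That mean separates the clones, so the fit also loses precision, and the drop does not measure what pollen accounts for. For 38 WRKY, NAC and ethylene genes the median standard error rose from 0.29 to 0.40. With the LAT52 gene as the covariate instead, 715 genes passed, of which 576 were among the 2520. When each library was rescaled to an equal sum, 2634 genes differed and 68.8% of them were higher in the strong clone, against 49.2% as deposited, with the median log2 difference of all genes going from 0.05 to 0.77.

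The 10 largest increases included enzymes and regulators besides the receptors. Cinnamoyl-CoA reductase 2 (PARG15239, linkage group 4), an enzyme of the lignin branch, was at 44.8 ± 26.2 FPKM in the strong clone and had 2 reads in the weak clone (5.30 ± 0.39, adjusted p = 0.00235). Endoglucanase 8 (PARG06847), which acts on cellulose, was at 108 ± 13.8 FPKM against 0.76, 0.0968 and 25.2 FPKM in the weak libraries, so that weak library 3 lay between the strong libraries and the other weak libraries (adjusted p = 0.0386). Basic 7S globulin 2 (PARG05624) differed by 4.52 ± 0.60, the chloroplast chaperone dnaJ 11 (PARG20891) by 4.36 ± 0.69, and SPL4 (PARG10753), a factor of the flowering transition, by 4.19 ± 0.84. A heavy metal-associated isoprenylated protein gene (PARG00260) was at 28.8 ± 3.12 FPKM against 0.762 ± 0.334. A gene without description on linkage group 3 (20965486 to 20967253) was at 23.5 ± 1.05 FPKM with 0 reads in the weak clone, at least 257-fold higher against a floor of 3 reads over the group.

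Among the 10 largest decreases, fatty acyl-CoA reductase 3 (PARG01275), an enzyme of wax and surface lipid synthesis, was at 87.5 ± 61.7 FPKM in the weak clone and 0.0445 ± 0.0404 in the strong clone (-6.12 ± 0.55, adjusted p = 0.00383). A WAT1-related transporter gene (PARG24255) had 0 reads in the strong clone and was at 45.7 ± 23.8 FPKM in the weak clone, so it was at least 872-fold lower against the same floor. Exopolygalacturonase (PARG13856), which degrades pectin, was at 11.6 ± 8.45 FPKM against 472 ± 236. Berberine bridge enzyme-like 8 (PARG11706) was at 3.27 ± 0.956 against 173 ± 98.7, and a C1 domain gene (PARG21418) at 5.28 ± 0.742 against 284 ± 145. Early light-induced protein 1 (PARG03490), a chlorophyll-binding protein of light stress, was at 1.28 ± 0.519 FPKM in the strong clone and 66.7 ± 29.5 in the weak clone (-4.82 ± 0.37). Genes without description, PARG13367 and PARG04635, differed by -5.99 ± 0.74 and -5.42 ± 0.44. Each of these 10 genes was lower in weak library 3 than in weak libraries 1 and 2, as LAT52 was.

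**Figure D2:**
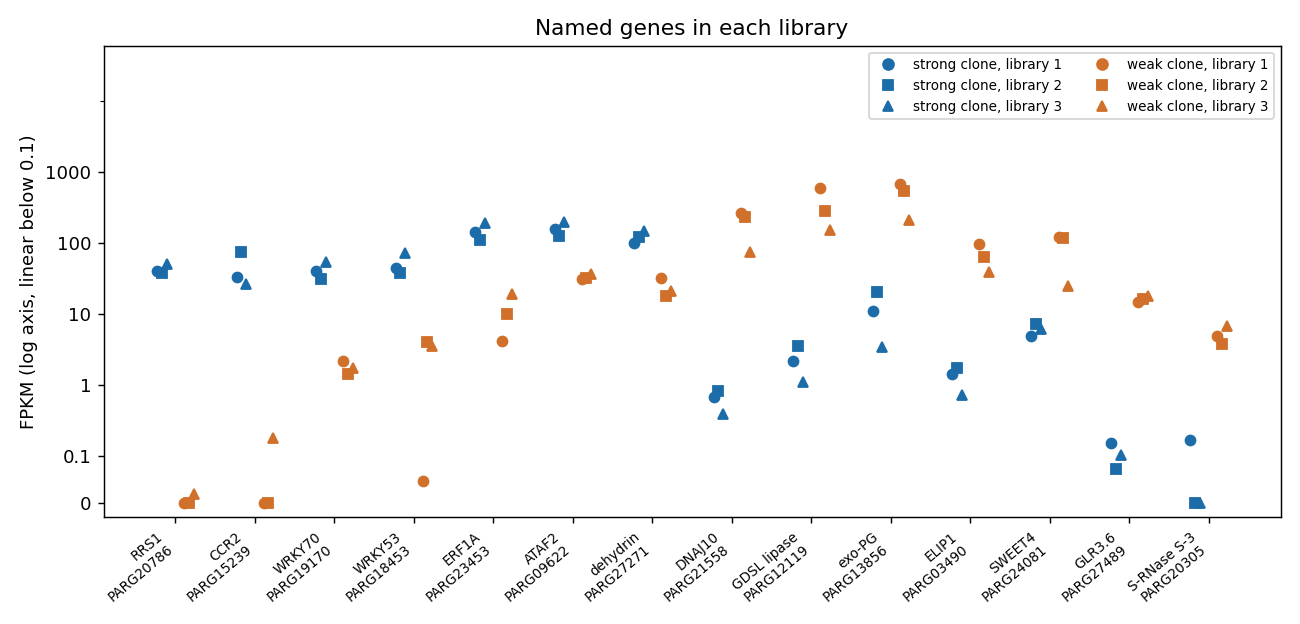
FPKM of 14 named genes in each of the 6 libraries, on a log axis that is linear below 0.1, with a point per library. RRS1 had 0, 0 and 0.0189 FPKM in the weak libraries and 37.7 to 51.2 in the strong libraries, and glutamate receptor 3.6 (GLR3.6) ran the other way, at 14.8 to 17.7 FPKM in the weak libraries. CCR2 is cinnamoyl-CoA reductase 2 and exo-PG is exopolygalacturonase.

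The share of genes named for the cold response that passed the test was near that of all tested genes, 15.3%. A gene that did not pass is not shown to be unchanged. Few simulated 2-fold changes were called, though at a stricter limit than in the real data. Of 7 upstream cold regulators, 1 was higher and 0 were lower (3 and 0 adjusted over the list alone). All 7 had a positive difference, with a list median of 0.92, and the list did not pass the camera test (adjusted p = 0.0948). CAMTA4 (PARG05795), of a family of calmodulin-binding activators of cold genes, was at 11.1 ± 1.29 FPKM against 2.95 ± 2.39 (1.78 ± 0.42, adjusted p = 0.0393). The genes described as ICE1, a factor that acts upstream of CBF genes, differed by 1.47 ± 0.47 (PARG24202, adjusted p = 0.0693) and 1.66 ± 0.51 (PARG12701, adjusted p = 0.0663) and did not pass the test. The CBF and DREB list matched 40 tested genes, of which 4 were higher and 2 lower (4 and 2 adjusted over the list alone). Of its matches 31 were not CBF or DREB genes, and among the calls were subunits of the CCAAT-binding factor NF-Y, such as NF-YA1 (PARG09364, 1.48 ± 0.19) and NF-YB7 (PARG09715, -3.28 ± 0.55). The most abundant matches, the transcriptional repressor Dr1 (PARG25045) and the Dr1-associated corepressor (PARG16780), differed by -0.35 ± 0.30 and -0.18 ± 0.22, adjusted p = 0.367 and 0.503. Among the 9 genes described as DREB proteins, 8 had a positive difference, and the median was 0.33. Past the threshold were 2 higher and 0 lower (2 adjusted over the list alone). They were DREB1D (PARG23731, 4.57, 6.17 and 5.85 FPKM in the strong and 0.717, 2.54 and 0.408 in the weak libraries) and a DREB3 gene (PARG15623), chosen after their values were seen.

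Of 58 genes for dehydrins, late embryogenesis abundant (LEA) and cold-regulated proteins, which protect cells from drying, 5 were higher and 2 lower (4 and 2 adjusted over the list alone). A dehydrin (PARG27271, linkage group 8) was at 122 ± 23.5 FPKM in the strong clone and 23.4 ± 7.23 in the weak clone (2.36 ± 0.28, adjusted p = 0.00771), and a LEA gene (PARG23904) differed by 2.10 ± 0.32. The most abundant dehydrin (PARG07069) was at 692 ± 56.6 against 1929 ± 898 FPKM and did not pass the test (-1.35 ± 0.56, adjusted p = 0.108). The neighbouring dehydrins on linkage group 8 did not pass it either, at -0.93 ± 0.43 (PARG27269, adjusted p = 0.134) and -1.21 ± 0.37 (PARG27268, adjusted p = 0.0644). Of 8 genes of proline metabolism 1 was higher and 1 lower (2 and 4 adjusted over the list alone), or 0 and 0 with equal sums, where the list median went from -0.69 to 0.079. Higher as deposited was delta-1-pyrroline-5-carboxylate synthase A (PARG19000), the enzyme that starts proline synthesis, at 47.2 ± 5.40 against 22.5 ± 7.75 FPKM. In the list of heat shock proteins and chaperones 14 of 180 were higher and 11 lower (14 and 10 adjusted over the list alone), or 19 and 5 with equal sums, where the list median went from -0.13 to 0.67. A DnaJ gene (PARG07009) differed by 3.00 ± 0.28.

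The WRKY, NAC, ethylene and jasmonate lists held more genes that were higher in the strong clone than lower. Of 39 genes with WRKY in their description 7 were higher and 1 lower (9 and 2 adjusted over the list alone). The WRKY domain was annotated in 36 tested genes, of which 6 were higher, so not all 7 carry that annotation. Besides RRS1 the 7 included WRKY70 (PARG19170), a regulator of salicylic acid responses, at 41.2 ± 11.1 FPKM against 1.76 ± 0.387 (3.91 ± 0.26, adjusted p = 0.00206), and WRKY53 (PARG18453), at 51.8 ± 18.5 against 2.54 ± 2.17. Of 49 NAC genes 11 were higher and 1 lower (14 and 2 adjusted over the list alone). ATAF2 (PARG09622) was at 158 ± 34.1 against 33.4 ± 3.00 FPKM and NAC90 (PARG01190) at 43.8 ± 15.7 against 4.37 ± 3.25. Of 87 ethylene genes 20 were higher and 5 lower (29 and 12 adjusted over the list alone). ERF1A (PARG23453), a factor of ethylene and defence responses, was at 149 ± 42.8 against 11.2 ± 7.59 FPKM and ERF5 (PARG19278) at 94.2 ± 29.5 against 13.3 ± 5.70. Of 57 jasmonate genes 13 were higher and 4 lower (17 and 6 adjusted over the list alone). MYC2 (PARG23125), the main jasmonate-responsive factor, differed by 1.78 ± 0.27 and TIFY10B (PARG15861), of the JAZ repressors, by 2.30 ± 0.39. Jasmonate O-methyltransferase (PARG07260) was at 71.5 ± 35.0 against 929.8 ± 526 FPKM. None of these 4 lists passed the camera test as a whole, with adjusted p values of 0.284, 0.109, 0.102 and 0.0948, and the lower pollen and higher photosynthesis means of the strong libraries went along with them.

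Of 93 abscisic acid genes 13 were higher and 5 lower (13 and 6 adjusted over the list alone). Receptors described as PYL4 differed by 2.36 ± 0.29 (PARG19136) and 1.90 ± 0.31 (PARG29278), an ABI5-like factor (PARG07789) by 1.15 ± 0.18, and abscisic acid 8'-hydroxylase 2 (PARG00651), which breaks the hormone down, by -1.91 ± 0.23. Of 84 auxin genes 3 were higher and 19 lower (13 and 27 adjusted over the list alone), and the list did not pass the camera test (adjusted p = 0.109). The list median of -0.32 turned to 0.41 when libraries were rescaled to equal sums, where 5 were higher and 12 lower. AUX28 (PARG20177), an Aux/IAA repressor, was at 9.62 ± 2.15 against 91.6 ± 37.9 FPKM. Of 28 gibberellin genes 2 were higher and 3 lower (2 and 3 adjusted over the list alone). Gibberellin 3-beta-dioxygenase 1 (PARG15458), which makes the active hormone, was at 0.0777 ± 0.0216 against 10.04 ± 8.17 FPKM. MYB44 (PARG07854, 3.30 ± 0.39) was among 20 higher and 17 lower of 203 MYB genes (20 and 18 adjusted over the list alone), or 21 and 9 with equal sums. bHLH35 (PARG03967, 3.18 ± 0.48) and BPE (PARG06229, a regulator of petal size, -2.81 ± 0.32) were among 7 higher and 7 lower of 88 bHLH genes (13 and 11 adjusted over the list alone), or 8 and 4 with equal sums.

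Of 157 cell wall remodelling genes 5 were higher in the strong clone and 32 lower (12 and 43 adjusted over the list alone), or 6 and 19 with equal sums. The list had a median log2 difference of -0.97 (-0.27 with equal sums and -0.51 with quantile scaling) and a camera adjusted p of 0.00057. That call was lost with an adjusted p = 0.697 with an estimated correlation. Besides exopolygalacturonase, the list held pectinesterase PPE8B (PARG27557) at 14.2 ± 2.47 against 107 ± 44.7 FPKM, and cellulose synthase-like G3 (PARG03596), which ran the other way at 21.02 ± 13.2 against 0.176 ± 0.105. Of 72 pollen genes 1 was higher and 7 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0708). Proline-rich protein 4 (PARG20908) was at 18.9 ± 3.76 against 478 ± 239 FPKM and callose synthase 5 (PARG09935), which builds the pollen wall, at 4.59 ± 1.17 against 15.1 ± 3.38. Of 28 MADS-box genes, a family of transcription factors with roles in flowering, 0 were higher and 4 lower (1 and 6 adjusted over the list alone). Among them were AGL61 (PARG09945, -3.44 ± 0.46) and SOC1 (PARG18142, -1.65 ± 0.38). The pollen mean of the libraries moved with the cell wall and MADS-box lists, and equal sums turned the MADS-box median from -0.45 to 0.18.

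Of 50 photosynthesis genes 18 were higher in the strong clone and 3 lower (30 and 4 adjusted over the list alone). The list had a median difference of 1.19 and a camera adjusted p of 0.000534, lost at adjusted p = 0.697 with an estimated correlation. Photosystem II protein W (PARG20183) was at 199.7 ± 18.2 against 78.8 ± 14.9 FPKM and the light-harvesting protein CP29.3 (PARG19072) at 139 ± 12.7 against 64.1 ± 2.66. Chlorophyll a-b binding protein 4 (PARG22825), like early light-induced protein 1, was lower, at 9.96 ± 0.841 against 80.9 ± 41.5. Of 147 cytosolic ribosomal protein genes only 2 were higher and 2 lower (1 and 1 adjusted over the list alone). A positive difference was seen in 129, and the camera adjusted p was 0.000534, lost at adjusted p = 0.737 with an estimated correlation. L2 (PARG28232), among the higher genes, is mitochondrial. The list means were 5.61 and 5.58 in weak libraries 1 and 2, 6.90 in weak library 3 and 6.74, 6.60 and 6.73 in the strong libraries, so weak library 3 lay above all of these.

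Sugar and phenolic metabolism held large single differences. Of 88 genes for raffinose, sucrose and starch breakdown 8 were higher and 10 lower (11 and 13 adjusted over the list alone), or 15 and 6 with equal sums, where the list median went from -0.58 to 0.18. A beta-amylase (PARG13690), which releases maltose from starch, was at 29.4 ± 5.48 against 6.49 ± 1.51 FPKM and sucrose-phosphate synthase 4 (PARG22676) at 1.09 ± 0.555 against 14.6 ± 6.02. Of 45 sugar transporters 3 were higher and 4 lower (9 and 12 adjusted over the list alone), or 3 and 1 with equal sums. SWEET4 (PARG24081) was at 6.05 ± 1.203 against 88.0 ± 55.2 FPKM and a sucrose transporter (PARG21984) at 22.6 ± 2.16 against 2.88 ± 1.82. Of 68 flavonoid genes 5 were higher and 10 lower (9 and 16 adjusted over the list alone), or 6 and 7 with equal sums. Flavonoid 3'-monooxygenase (PARG23247), which hydroxylates anthocyanin precursors, was at 39.7 ± 6.94 against 186 ± 66.5 FPKM. Of 58 lignin and phenylpropanoid genes 7 were higher and 8 lower (9 and 15 adjusted over the list alone), or 7 and 5 with equal sums. Of 35 lipid desaturases and phospholipases 3 were higher and 4 lower (4 and 9 adjusted over the list alone), or 5 and 2 with equal sums. A chloroplast delta-7 desaturase (PARG10102) was at 14.3 ± 3.07 FPKM against 0, 0 and 3.57 in the weak libraries. Of 98 antioxidant enzymes 11 were higher and 8 lower (17 and 12 adjusted over the list alone). Peroxidases went both ways, at 3.44 ± 0.33 (peroxidase 15, PARG00008) and -2.96 ± 0.30 (peroxidase 4, PARG00379).

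Of 142 calcium signalling genes 17 were higher and 15 lower (20 and 18 adjusted over the list alone), or 21 and 6 with equal sums, where the list median went from -0.29 to 0.48. Cyclic nucleotide-gated channel 1 (PARG11782) was at 8.57 ± 1.71 against 0.0845 ± 0.146 FPKM. Of 39 MAP kinase genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone), the kinase kinase 9 (PARG25230, 2.76 ± 0.40). Of 116 pathogenesis-related genes 8 were higher and 15 lower (12 and 16 adjusted over the list alone), or 15 and 9 with equal sums, where the list median went from -0.07 to 0.70. PR-4A (PARG01365) was at 36.1 ± 12.9 against 7.70 ± 1.39 FPKM and MLP-like 328 (PARG06822) at 9.54 ± 4.11 against 197 ± 99.98. Of 23 aquaporins 1 was higher and 1 lower (0 and 0 adjusted over the list alone), of 106 histone and cell cycle genes 7 and 5 (1 and 3 adjusted over the list alone), and of 72 genes of autophagy, senescence and cell death 5 and 4 (2 and 2 adjusted over the list alone, or 9 and 3 with equal sums, where the list median went from -0.20 to 0.55). In the list of pistil and self-incompatibility genes 1 of 19 was higher and 4 were lower (2 and 5 adjusted over the list alone). Ribonuclease S-3 (PARG20305), an S-RNase by which the pistil rejects pollen of its own type, had 2 reads in the strong clone and was at 5.14 ± 1.497 FPKM in the weak clone (-2.52 ± 0.24, adjusted p = 0.00436). The search for words of other organisms matched 57 genes, 5 higher and 6 lower (5 and 6 adjusted over the list alone), or 6 and 4 with equal sums. They include retrotransposon descriptions and plant genes such as glutamate receptor 3.6 (PARG27489), an ion channel gene at 0.109 ± 0.0406 against 16.3 ± 1.49 FPKM.

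**Figure D3:**
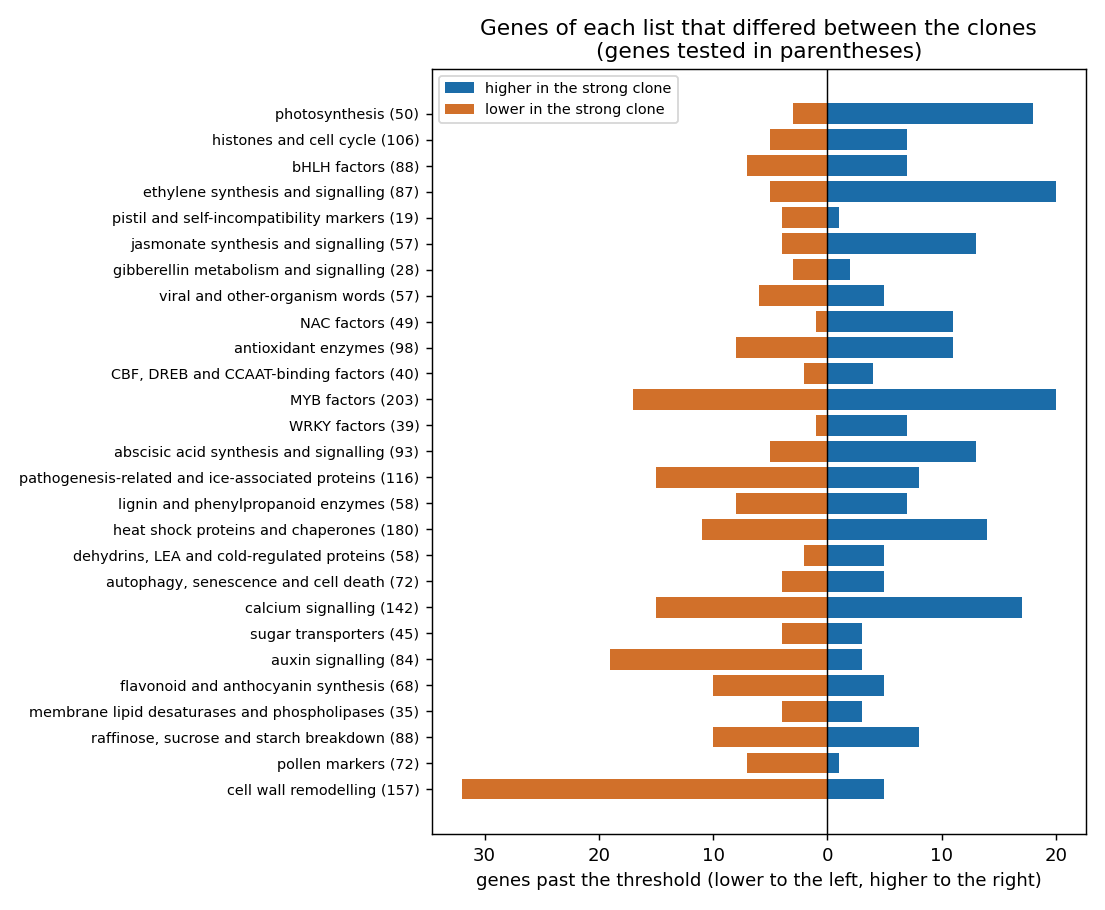
Number of genes in each list that were higher (right) or lower (left) in the strong clone, with the number tested in parentheses, for lists with at least 5 such genes, ordered by the list's median difference. Photosynthesis (18 higher, 3 lower) and ethylene (20 and 5) lean to the right, and cell wall remodelling (5 and 32) and auxin (3 and 19) to the left.

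Some genes were listed in one clone only. At 1 FPKM or more in all 3 libraries of a clone and below 0.1 FPKM in all 3 of the other, 159 genes were listed, 62 in the strong and 97 in the weak clone. Of these, 50 and 67 had 0 reads in the other clone. Strong-only genes included RRS1 and the subtilisin-like protease SBT1.8 (PARG07779), at 10.2, 11.2 and 8.74 FPKM with 0 in each weak library, the latter chosen after its values were seen. Weak-only genes included fatty acyl-CoA reductase 3, the WAT1-related gene and calmodulin-like protein 2 (PARG13181), at 11.6, 16.2 and 4.68 FPKM with 0 reads in the strong clone, at least 197-fold lower against the floor. Without weak library 3 the number listed was 383, of which 221 were in the strong and 162 in the weak clone, so that the larger number lay in the strong clone.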

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

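The tests, filters, gene lists and most alternatives were fixed before the data were examined, while the voom fit, the covariate fits, the comparison with weak library 3 alone and equal sums for the gene lists, and the protein families with all their alternatives, were added after the data had been seen. The count of 2520 genes stayed within 1.5 times under both other pseudocounts (1886 and 2263), no filter (2344), a lower filter (2943), equal sums (2634), TMM-type (2581), quantile (3187) and upper-quartile scaling (2634), no trend (2344), a robust fit (2210) and voom (2208, of which 2009 were among the 2520). A mean of at least 5 FPKM left 1015 genes (917 at 2-fold or more) of 11469 tested, of which 1014 were among the 2520. Library weights, whose estimation stopped before its tolerance was reached, gave 12307 (8041), the pollen covariate 59 (59), the LAT52 covariate 715 (676) and weak library 3 alone 576 (575), where the lone sample is assumed to vary like the strong libraries. Leaving out each library gave 166 to 12075 genes (166 to 7885 at 2-fold or more), the highest without weak library 3, and 161 genes, 87 of them higher in the strong clone, were called in all 6 of these fits and with all libraries. The causes were not tested. Equal sums moved the share of higher calls from 49.2% to 68.8%.

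With the replicate number as a block, 6439 genes passed (5379 at 2-fold or more) and 6 lists. Whether the numbers pair the libraries could not be told. Deviations from the clone means correlated at -0.24, 0.59 and 0.61 between equal numbers, and 3 of the 6 libraries correlated best with their own number. With 3 libraries per clone these deviations depend on each other, so they can neither show nor exclude pairing.

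The 159 genes listed in one clone only were 117 at exactly 0, 25 at 5 FPKM or more, 247 with a limit of 0.3, 173 to 383 when a library was left out (383, with 221 in the strong and 162 in the weak clone, without weak library 3) and 233 against weak library 3 alone. The 3 lists past the threshold were 0 with an estimated correlation, 1 by fry, 9 with equal sums, 0 with the pollen covariate, 6 against weak library 3 alone and 3 to 8 when a library was left out. The ribosomal list reversed with the pollen covariate (adjusted p = 0.921) and against weak library 3 alone (adjusted p = 0.00697 at the fixed correlation, under the same assumption on the lone sample). Genes that had not passed and changed sign were Dr1 (PARG25045; log2 difference 0.48 with equal sums, 0.17 with quantile scaling, 0.16 and 0.34 with the pollen and LAT52 covariates, 0.22 against weak library 3), the Dr1-associated corepressor (PARG16780; 0.64, 0.21, 0.043, 0.18 and 0.16 in the same order) and the dehydrin PARG07069 (0.12 with quantile scaling). Of 136 named genes, 12 kept both direction and side of the threshold in every alternative. The difference in detected genes, 455 as reported, was 249 to 734 in the alternatives, the lowest without weak library 1 and the highest without weak library 3. The difference in the share of the 10 top genes, -3.23 percentage points, was -2.67 to -4.21 when a library was left out, and that of the 50 top genes was -10.5. The 12 protein families over-represented among the calls were 7 to 16 under the pseudocounts, scalings, variance models, voom and the filters other than a mean of 5 FPKM, which gave 6. They were 0, 3 and 1 without strong library 1, 2 or 3, and 5, 2 and 25 without weak library 1, 2 or 3. Settings with few calls leave little that can pass this test. Library weights gave 32, the replicate block 21, weak library 3 alone 4, the LAT52 covariate 5 and the pollen covariate 0. Depth limits what 0 reads can show to the bound that 3 reads give.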

Other observations

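The tests of the scaling, of weak library 3, of tissue shares for genes of one clone, of protein families and of other splits for gene counts were chosen only after the results were seen. Among protein families, tested by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 210 families of at least 15 tested genes, 5 were over-represented among the genes higher in the strong clone and 7 among those lower. NB-ARC domain genes, the class of intracellular immune receptors, led the first group with 26 of 81 higher where 6.10 were expected (adjusted p = 2.01e-08), followed by AP2 domain genes (18 of 65, 4.89 expected), S-locus glycoprotein domain kinases (8 of 26), NAM domain genes (11 of 50) and TIR domain genes (10 of 43). Lower in the strong clone were cytochrome P450 genes (25 of 110, 8.56 expected, adjusted p = 0.000181), GDSL lipases (13 of 41), 2OG-Fe(II) oxygenases (15 of 71), MatE transporters (9 of 26) and xyloglucan endotransglycosylases (8 of 19). Genes of a family lie close together and share history, so they are not independent draws. A gene can also count in more than 1 family, so the families are not all separate results. Differences in sequence or gene copies between the clones were not tested for these families. These families rest on the 2520 calls, made between clones whose libraries also differ in their mean pollen and photosynthesis levels. None passed with the pollen covariate, which left 59 calls, and none without strong library 1, which left 166. So few calls leave little that can pass over 210 families, so these losses say little about the families. NB-ARC genes were lost with quantile scaling (Fisher adjusted p = 0.229) and with a mean of at least 5 FPKM (0.367). NB-ARC genes passed in 3 of the 6 fits that leave out a library, GDSL lipases in 2, AP2, P450, xyloglucan endotransglycosylase and family 16 glycosyl hydrolase genes in 1 each, and the other 6 families in 0. The number of calls limits this tally too, since leaving out a library left 166 to 610 calls, except 12075 without weak library 3. Over all 24 settings the NAM family passed in 3, TIR and S-locus in 6, MatE in 8 and 2OG-Fe(II) oxygenases in 10.

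Several genes passed even with the pollen covariate. An AWPM-19-like membrane protein gene (PARG03795), of a family tied to freezing tolerance in cereals, was at 112, 130.3 and 136 FPKM in the strong libraries and 10.5, 7.803 and 8.502 in the weak libraries, with a covariate-adjusted log2 difference of 3.73. A gene without description (PARG28181) was at 104, 93.8 and 109 FPKM against 8.24, 9.33 and 10.9, and boron transporter 1 (PARG16179) at 4.24, 3.74 and 3.51 against 175, 161 and 71.0. Isoeugenol synthase 1 (PARG09330), an enzyme of floral scent, was at 0.182, 0.694 and 0.309 FPKM against 10.6, 11.96 and 11.4. These were chosen after their values were seen, and 20 of the 59 genes past the threshold with that covariate were among those listed in one clone only.

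The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: for gene counts 1 of 10, the real one, gave as many genes, 2520 against at most 0 in the others, and 1 of 10 as many at 2-fold or more, 2205 against at most 0. For gene lists, 8 of the 10 splits gave at least 3 lists, and the highest other split gave 10, which points to a structure of the libraries that the camera test reads as list changes.

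The strong clone has a lower mean pollen level, so clone and pollen level overlap in these libraries. The authors' scaling is argued against as the whole cause, because 72.9% of the 2520 genes stayed past the threshold in their direction with equal sums. This held for 89.3% of the higher genes, which equal sums favour, and for 57.0% of the lower genes, against which they work. A mislabelled or mixed weak library 3 is argued against, because only 73.2% of 41 genes that were at 5 FPKM or more in all strong libraries and absent from weak libraries 1 and 2 were present in weak library 3, and 10 had 0 reads there, while all 36 genes of the opposite kind were present. A different share of pollen, for instance from flowers at another stage, may account for part of it: strong libraries 2 and 3, which differ in pollen level, differed in the direction this predicts in 76.1% of the called genes, but in 75.6% of the other genes too, so this does not single out the called genes. Whether stage, frost injury or the clones' own anthers set the pollen level was not tested.

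The 159 genes listed in one clone only were set against the number that counting noise would leave there if the other clone held each expressed gene at a fixed ratio. For the strong-only genes, a lower share of green tissue in the weak clone is argued against as the whole cause. With all 15179 genes at 1 FPKM or more in the strong libraries held at the lowest weak to strong ratio among 22 abundant photosynthesis genes, 0.150, 4.39 would be listed, and 62 were. Shares of other tissues and a difference in stage were not tested. For the weak-only genes, a lower share of pollen in the strong clone was taken as a fixed ratio. In that form it is argued against for the 14 that were at 5 FPKM or more in all weak libraries. Of 8937 genes at that level, 0.0878 would be listed at the lowest strong to weak ratio among 27 abundant pollen list genes, 0.0395, below the LAT52 ratio of 0.269. For the other 83 as a set, a lower share of pollen cannot be told apart from a clone difference. At the lowest ratio 431 of 4909 genes would be listed, and 0.00264 at the LAT52 ratio. Of the 97, 33 had fewer reads in the strong clone than the lowest ratio gives by counting error (Bonferroni p under 0.05 over 13846 genes), 13 of the 14 and 20 of the 83. Of the 97, 77 were lower in weak library 3 than in libraries 1 and 2, as LAT52 was. A fixed ratio does not cover genes that follow the stage of the flower, so a difference in stage stays open for all 97. A sequence or gene-copy difference between the clones remains a candidate explanation: 11 pairs of genes listed in the same clone only were neighbours along the linkage groups among expressed genes, against a mean of 0.770 and at most 5 in 10000 random draws (permutation p = 0.0001, the smallest they can give), for example the fatty acyl-CoA reductase genes PARG01275 and PARG01277 and a pair of flavonoid glucosyltransferase genes, PARG21184 and PARG21185. Neighbouring copies that are regulated together would give the same value, as would pieces of a single gene that are listed apart. PARG13550 lies within the span of its partner PARG13548 on linkage group 4, and PARG21184 and PARG21185 have the same description. Runs such as PARG14919, PARG14920 and PARG14921 count as more than 1 pair. Such cases were not set aside, so the number of pairs may be too high, and no sequence was analysed here.

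The 38 WRKY, NAC and ethylene genes called higher in the strong clone were examined with covariates. With the pollen list mean as a covariate their median log2 difference went from 1.84 to 1.31 (71.2% of its value, quartiles 0.87 and 1.79), all 38 stayed positive and 2 passed the threshold. With the photosynthesis list mean as a covariate it went to 1.27 (68.9%, quartiles 0.85 and 1.78), again with 38 positive and 2 past the threshold. Their quartiles without a covariate were 1.27 and 2.88. The median standard error rose from 0.29 to 0.40 with either covariate, and the largest p called fell from 0.00765 to 0.000178 (pollen) and 0.000265 (photosynthesis). With only the difference taken from the covariate fit 17 and 18 of the 38 passed, with only its error and degrees of freedom 22 and 19, and with both, at the p limit used without a covariate, 10 and 11. The smaller difference, the larger error and the stricter limit thus each ended calls. A part played by pollen or green tissue cannot be told apart from a clone difference here, since both list means separate the clones in these 6 libraries. As a hypothesis, a stronger frost or defence response of the resistant clone, or a different injury at the time of collection, stays open. It was not tested, because no unfrosted flowers were analysed. With a single clone of each kind, resistance also cannot be told apart from any other difference between the clones.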
